A study of Mus musculus with 2 samples.

How the data were processed

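Epithelial cells of mouse oviduct were dissociated with enzymes, sorted with antibodies to Epcam and CD45, and made into 10x Chromium 3' V2 libraries, per the labels, 1 from adult mice at estrus and 1 at postnatal day 4 (P4). The submitters' processing notes name Cell Ranger (version not given in the sources used here), Seurat 2.3.4 and the genome build mm10, without saying which step each did. The authors deposited 3 tables of raw counts (UMI per gene and cell: adult, P4 and merged), with no normalization, and 3 tables with a cluster number per cell. The values were checked to be whole numbers with totals that differ between cells. Gene positions come from GENCODE M21 on GRCm38.

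The adult table lists 27998 genes, that of P4 lists 53573 and the merged one 54674, and 26897 genes are in both single tables. The adult table has 807 columns under 2 prefixes, of which 401 barcodes occur under both, and 406 distinct barcodes. For a repeated barcode the column of the first prefix was used. For genes outside the other table, 1.79% of adult and 13.4% of P4 UMI were left out of comparisons between ages, which used totals over the shared genes. The merged table holds 1039 columns (403 distinct adult cells and 239 P4 cells). Its counts equal those of the single tables in every shared column, so it was used for the merged clusters and as an alternative.

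A level is the sum of counts of a gene over a group of cells divided by the group's total and multiplied by 10000. Levels have exact 95% Poisson intervals, ratios of levels an exact conditional interval, and shares of cells exact Clopper-Pearson intervals; for a share of 0 the limit given is 3 cells over the number of cells. Folds were computed with a pseudocount of 0.1 per 10000. Where a side had 0 counts the fold is given as a bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its interval. A gene was measured in a comparison if at least 10% of cells on either side had a UMI. Genes chosen by the size of their fold also needed that share, and a pooled count of at least 20, on the higher side. Members of the fixed lists had no minimum count, so some rest on few counts. No p-values were computed, since each age has 1 library and cells are not replicates.

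Named genes followed a fixed rule: per comparison the 12 measured genes with the largest fold in each direction, at least 2-fold, without ribosomal protein genes, mitochondrial genes and Gm or Rik models; for a cluster against the rest the top 8; besides these, members of the fixed lists that differed at least 2-fold; and always Wt1, Pax2, Pax8, Foxj1, Ovgp1 and Epcam. The fixed lists cover regional transcription factors, Hox, steroid hormone, secreted product, imprinted and fetal growth, Notch, Wnt, retinoic acid, Hedgehog, Tgfb and Bmp, antigen presentation and interferon, extracellular matrix, dissociation stress, stem and basal cell, ribosomal protein and mitochondrial genes, and markers of 11 cell types. For each list the median log2 fold of measured members was compared with 10000 random lists of the same size, matched on level in 20 bins. From the rule's genes the text leaves out Rps26-ps1, Rpl9-ps6, Rps27rt, Rpl13a-ps1, Wdr89, Vps8 and Gins1. Their P4 levels may depend on reads shared with other genes or on the annotation, which was not tested on reads.

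A cluster was named after the marker list with the highest mean percentile of its folds among lists with at least 3 detected markers. The lists, the rule, the comparisons, the tests and most alternatives were fixed before the data were examined. The following were chosen after the data were seen: 1 column per adult barcode; taking general epithelial markers as a parent class, so that adult cluster 4 counts as secretory-like and P4 cluster 1 as secretory-type; adding cluster 3 to the multiciliated-like class, which the naming rule gives; thresholds of 10 smooth muscle UMI and 30 multiciliated marker UMI per 10000 (7 P4 cells lie between 20 and 40); the comparisons of adult cluster 3 with 1 and 5 with 0; the pairs of genes counted in the same cells other than Wt1 and Pax2; and 3 of the pairs in the comparison across genes. The plan asked for the main pair of P4 clusters without multiciliated cells, and P4 has clusters 0 and 1 alone, so these were used although cluster 0 holds 6 cells with multiciliated markers.

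Median depth was 3232 UMI and 1588 genes per cell in the adult library and 7585 UMI and 2865 genes at P4. Mitochondrial genes took a median of 4.00% and 0.844% of UMI and ribosomal protein genes 15.1% and 24.6%. For comparisons at equal depth, cells with at least 1000 UMI were thinned to 1000 (322 adult and 263 P4 cells). Other alternatives were a mean over cells in place of pooling, a pseudocount of 0.5, no filter on the share of cells, a filter of 25%, leaving out cells with 2 or more non-epithelial markers, the 5% of cells with the most UMI, proliferating cells or stress and cell cycle genes, another denominator, and own Leiden clusters (20 components, 15 neighbours, 2000 variable genes). A value under an alternative counts as unmoved if it stays within the 95% range of 200 Poisson draws of the counts, or, for a share of cells, within its exact interval. No doublets were called and no background RNA was estimated, and leaving out the cells with the most UMI was the step aimed at doublets. An alternative for values on a log scale was not needed, as all values are counts.

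Counts with known changes of 4-fold and 8-fold were simulated for adult secretory-like against multiciliated-like cells and for P4 against adult. In both, 100% of changed genes were recovered, and of unchanged genes 99.5% and 100% stayed within 2-fold. Changed genes were taken from those with high expected counts, and the draws held counting error alone. Lists of 20 unchanged genes lay at percentiles 86.7 and 87.8. Smaller clusters and genes with few counts were not simulated. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9. Sequence reads were not used here, and some results for single genes are not reported here.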

Results

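The series holds single-cell RNA-seq of mouse oviduct epithelium (C57BL/6) from 2 libraries, an adult library at estrus and a library at postnatal day 4 (P4). The oviduct carries the egg from the ovary to the uterus, and its lining holds multiciliated cells, which move fluid along the tube, and secretory cells, which make that fluid. The question named by the series is whether the distal end, near the ovary, and the proximal end, near the uterus, are lined by separate lineages. Neither the labels nor the cluster tables say which cluster is distal or proximal, so clusters were compared by the authors' numbers.

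The adult table held 1401641 UMI in 406 cells (median 3232 per cell, range 502 to 16207) and that of P4 cells held 2123202 UMI in 263 cells (median 7585, range 1331 to 23372). Levels are pooled UMI per 10000 UMI of a group, with exact 95% Poisson intervals in brackets. These cover counting error only: each age is 1 library, so no value could be checked against a replicate, and cells were not treated as replicates. A count of 3, the floor used here, equals 0.0214 per 10000 in the adult library and 0.0141 in the P4 library. The adult table lists 401 barcodes under both of its column prefixes, and the paired columns differed by less than sampling noise (mean squared difference over sum 0.140, against 1.40 or more for other pairs of cells of a cluster). Each barcode was therefore counted once. Ptprc, which encodes the leukocyte antigen CD45 used in the sort, had 0 UMI in the listed cells of both libraries.

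Key genes, on mouse genome build GRCm38 (mm10), are Ovgp1, which encodes the oviduct glycoprotein coating the egg (chromosome 3, 105973711 to 105987423, plus strand), and Foxj1, a master regulator of motile cilia (chromosome 11, 116330704 to 116335399, minus strand). Transcription factor genes of the urogenital tract are Wt1 (chromosome 2, 105126529 to 105173616, plus strand), Pax2 (chromosome 19, 44756045 to 44837871, plus strand) and Pax8 (chromosome 2, 24420560 to 24475599, minus strand). Epcam, the epithelial surface protein used in the sort, lies on chromosome 17 (87635979 to 87651129, plus strand). Genes that share reads with copies, such as ribosomal protein genes and their pseudogenes, are uncertain in every value given here.

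The adult cells carry 5 cluster numbers of the authors, 0, 1, 3, 4 and 5, and the merged cells carry 0, 1, 2, 4 and 6. Some numbers are thus absent, and whether cells under them were left out could not be seen here. Cluster 1 held 183 of 406 cells (45.1%, exact binomial interval 40.2 to 50.1) and cluster 0 held 130 (32.0%, 27.5 to 36.8), while clusters 3, 4 and 5 held 37, 31 and 25 cells. Clusters 1 and 3 carried the multiciliated genes of the fixed list and are called multiciliated-like (mean percentile of marker folds 99.6 and 85.0). Cluster 0 had secretory markers on top among lists with enough detected genes (76.9). Cluster 4 scored highest for general epithelial markers (61.6) and had Ovgp1 among its top 10 genes. Clusters 0 and 4 are called secretory-like, and cluster 5, which scored highest for smooth muscle genes, is kept by number. The P4 cells formed 2 clusters, cluster 0 with 168 of 263 cells (63.9%, 57.8 to 69.7) and cluster 1 with 95 (36.1%, 30.3 to 42.2). P4 cluster 0 scored highest for multiciliated markers (99.8, with 9 of 15 detected), so the naming rule would call it multiciliated, but it is kept by number because 6 of its cells hold much of that signal. P4 cluster 1 scored highest for epithelial markers (66.0), then for secretory ones (54.8), and serves as the secretory-type cluster of that age. Secretory markers hardly set it apart from P4 cluster 0. Of 7 measured, 2 were higher and 5 within 2-fold (median log2 fold 0.02, percentile 49.9 among random lists). These shares depend on dissociation, on sorting and on any cells left out, and are not tissue proportions. The clusters were made from expression, so the genes that define them describe them and are not independent results.

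**Figure D1:**
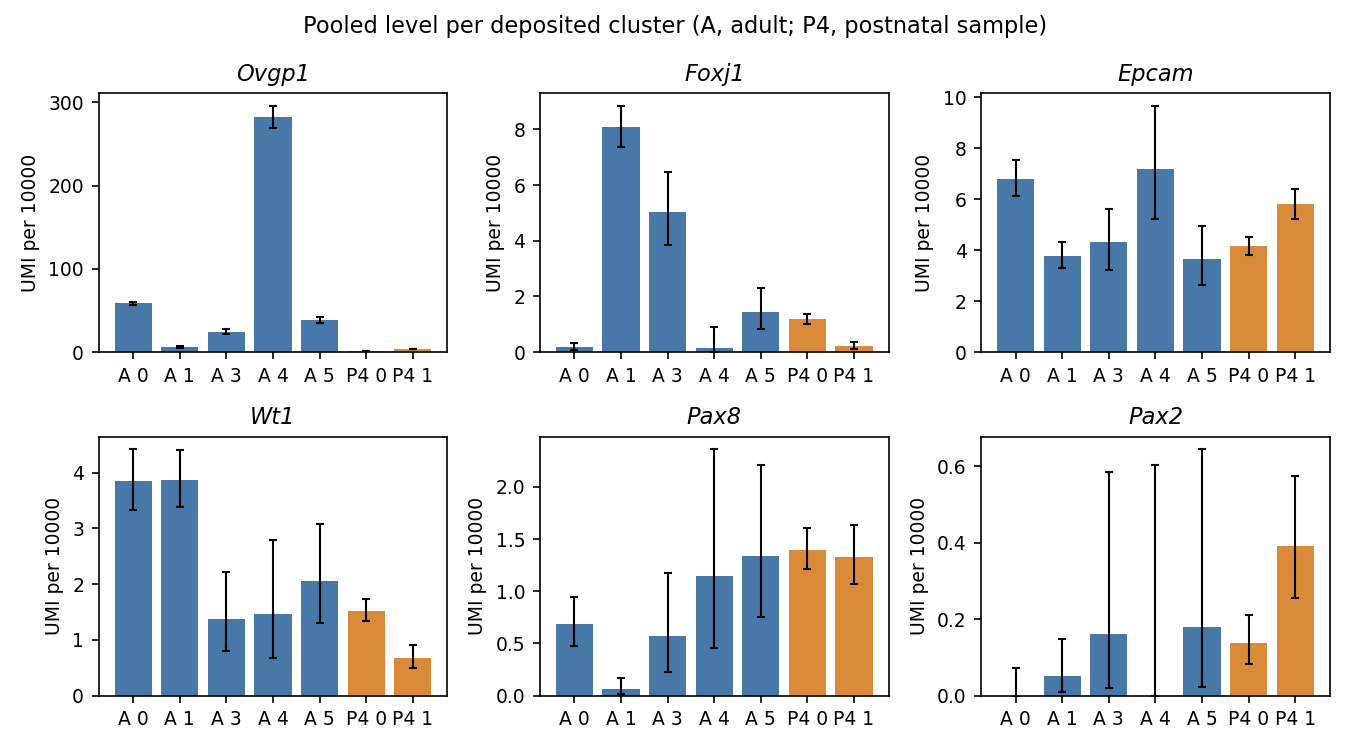
Bars give the pooled level (UMI per 10000 UMI) of Ovgp1, Foxj1, Epcam, Wt1, Pax8 and Pax2 in each adult (A) and P4 cluster of the authors, with 95% Poisson intervals. Ovgp1 is highest in adult cluster 4 (282.1), Foxj1 in adult clusters 1 and 3, and Wt1 is lower in P4 cluster 1 (0.679) than in P4 cluster 0 (1.53).

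Adult secretory-like cells (161 cells, 573970 UMI) and multiciliated-like cells (220 cells, 715597 UMI) differed in the genes that carry out their work. Ovgp1 stood at 82.5 (80.1 to 84.8) against 9.33 (8.64 to 10.1), 8.75-fold higher in secretory-like cells. The antibacterial iron and siderophore binding proteins encoded by Lcn2 and Ltf were 19.5-fold and 12.4-fold higher, the chaperone gene Clu 11.8-fold and Agr2, a disulfide isomerase gene of mucus-secreting cells, 15.5-fold. Wfdc18, a small secreted protein gene, stood at 75.6 against 5.70. Cilium genes went the other way: Tmem212 was 65.1-fold, the dynein light chain gene Dynlrb2 55.4-fold, Ccdc153 51.6-fold and Foxj1 27.9-fold lower in secretory-like cells. All 15 multiciliated markers were at least 2-fold lower (median log2 fold −5.11), while 4 of 7 measured secretory markers were higher (median 1.71).

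Further gene lists also differed between these classes. They are not independent of the naming: the secreted products list shares Ovgp1 with the secretory markers, and the clusters were made from expression. Of 12 measured genes for oviduct fluid and secreted products, 6 were at least 2-fold higher in secretory-like cells, 2 lower and 4 within 2-fold (median log2 fold 1.37, percentile 100 among 10000 random lists of like level). Antigen presentation genes were higher for 4 of 7 (H2-K1, H2-D1, B2m and Psmb8, median 1.32), and 68 of 82 ribosomal protein genes were higher (median 1.27). Dissociation stress genes moved with them: 4 of 14 were higher (Ier3, Egr1, Fosb and Zfp36) and 1 lower (median 0.78). Among steroid hormone genes, 4 of 8 were higher, with the estrogen receptor gene Esr1 at 1.60 against 0.629, and 1 lower, the growth factor gene Areg, with 1 count in secretory-like cells (ratio interval of multiciliated-like over secretory-like, 13.5 to 3073). In the Wnt list Dkk3 and Rspo1 were higher and Wnt4 (0.418 against 1.87) and Wnt11 lower. Pax8 was 3.28-fold higher in secretory-like cells (0.732 against 0.154). Wt1 did not differ beyond counting error, at 3.59 against 3.44 (ratio interval 0.863 to 1.26), and Epcam was within 2-fold. Pax2 had a UMI in 0 of 161 secretory-like cells, which allows a share of cells with a UMI of up to 1.86% (3 of 161) and sets no limit on cells that express it below detection, and in 5 of 220 multiciliated-like cells.

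Ovgp1 had a UMI in 90.7% of secretory-like cells and in 38.6% of multiciliated-like cells, with median depths of 3221 and 3194.5 UMI. The log2 fold of Ovgp1, 3.13, was 3.98 when every cell weighed alike, 3.72 when cluster 1 alone stood for multiciliated cells and 2.64 when cluster 0 alone stood for secretory cells.

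Adult cluster 4 (31 cells, 61113 UMI) differed from cluster 0 (130 cells, 512857 UMI) in some genes of secreted products. Ovgp1 was 4.80-fold higher in cluster 4, at 282.1 (268.9 to 295.7) against 58.7 (56.6 to 60.8). Dcpp3, a secreted protein gene, was 5.69-fold, Agr2 5.56-fold and the calcium buffer gene Calb1 5.35-fold higher. Also among the 12 genes with the largest folds were Fkbp11 (4.82-fold), the signal peptidase gene Sec11c (4.65-fold), the chaperone gene Dnajb11 (4.42-fold) and Creld2 (4.14-fold), whose products act in the endoplasmic reticulum. No fixed list covers that function, so it was not tested as a group. Cluster 0 carried genes not counted in cluster 4, so only bounds can be given: Igfbp3, an insulin-like growth factor binding protein gene, was at least 6.32-fold, the tight junction gene Cldn4 at least 4.17-fold and the cell cycle inhibitor gene Cdkn1a at least 2.94-fold higher in cluster 0. Socs3, a feedback inhibitor gene of cytokine signals, had 2 counts in cluster 4 (ratio interval of cluster 0 over cluster 4, 4.71 to 142.4).

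Wt1 was 2.51-fold lower in cluster 4, at 1.47 (0.673 to 2.80) against 3.84 (3.32 to 4.42). Pax2 had no UMI in either cluster, Pax8 stood at 1.15 against 0.682 and Epcam at 7.20 against 6.81. Of 4 measured Hox genes, which mark position along the body axis, 1 was higher, Hoxb6 (1.64 against 0.624, ratio interval 1.15 to 5.47), and 2 were within 2-fold. The other, Hoxc4, had 0 counts in cluster 4 and stood at 0.468 in cluster 0, under the floor of cluster 4 (0.491), so no difference was detectable (list median −0.40, or 0.03 with that gene at its bound). All 13 measured dissociation stress genes were lower in cluster 4 (median −1.80, percentile 0), with Fos at 8.84 against 31.3 and Jun at 5.73 against 20.7. The secreted products list had 4 of 11 genes higher (Ovgp1, Lcn2, Ctsl and Cst3), and 1, Muc1, had too few counts in cluster 4 (1) for a clear difference. Secretory markers did not move up as a group: of 7 measured, 1 was higher, 2 lower and 4 within 2-fold (median −0.18). Of 4 measured multiciliated markers 2 were higher in cluster 4 and 2 within 2-fold (median 0.99). The Notch target gene Hes1 was lower, at 1.64 against 6.75. Cluster 4 cells held a median of 1185 UMI against 4107.5, and only 12 of the 24 genes with the largest folds were also chosen when every cell weighed alike.

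Adult cluster 3 (37 cells, 123177 UMI) was compared with the other multiciliated-like cluster, 1 (183 cells, 592420 UMI), a comparison chosen after the cluster values were seen. Cldn4 stood at 9.09 in cluster 3 and had 3 counts in cluster 1 (ratio interval 59.9 to 883.8). Wfdc12 was 49.9-fold and the small heat shock gene Hspb1 33.0-fold higher in cluster 3, and Krt17, a keratin gene of stressed and basal epithelium, at least 72.1-fold. The surface protein genes Ly6a and Ly6c1 were 19.9-fold and 17.4-fold higher and Igfbp3 16.6-fold. All 3 measured Hox genes, Hoxb5, Hoxb6 and Hoxb7, were higher in cluster 3 (median log2 fold 1.96), with Hoxb6 at 1.30 against 0.169. Ovgp1 was 3.94-fold higher (24.6 against 6.16). Genes lower in cluster 3 included Foxa2, a transcription factor gene of endoderm and glands (at least 2.98-fold), the binding protein gene Igfbp2 (at least 5.34-fold), Tshz2 (at least 8.11-fold) and Wt1 (2.68-fold, 1.38 against 3.87).

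Of the 15 dissociation stress genes 11 were higher in cluster 3 (median 1.5), as were 3 of 5 secretory markers (1.82), 5 of 8 epithelial markers (1.15) and 4 of 9 antigen presentation and interferon genes (1.0). Multiciliated markers were mostly within 2-fold (14 of 15), with Tmem212 lower at 6.33 against 18.8 and Foxj1 at 5.03 against 8.09.

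Adult cluster 5 held 7 cells with 42 to 156 UMI of smooth muscle genes among its 25, and the other 18 cells had at most 4. The 18 cells (54051 UMI) were set against cluster 0, also after the values were seen. Serpina1e, a protease inhibitor gene (chromosome 12, 103946931 to 103958975, minus strand), stood at 18.1 and had 3 counts in cluster 0 (ratio interval 103.0 to 1529). Fxyd4, a regulator gene of the sodium pump, was 31.1-fold higher, the interferon-induced gene Ifitm1 17.8-fold, the secreted glutathione peroxidase gene Gpx3 9.95-fold and Wfdc2, a protease inhibitor gene of reproductive epithelium, 7.79-fold. Lower were Igfbp3 (at least 5.59-fold), Mfge8 (at least 4.43-fold), Msln (at least 4.15-fold) and the intermediate filament gene Vim (at least 2.42-fold). Wt1 stood at 0.740 against 3.84. Of 13 dissociation stress genes 1 was higher, 5 lower and 7 within 2-fold (median −0.55); of the 5, Nr4a1 had 3 counts and a ratio interval that includes 1.

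The P4 clusters, 1 (95 cells, 662573 UMI) and 0 (168 cells, 1460629 UMI), differed in genes of cilium formation, in part through 6 cells described below. Higher in cluster 1 were the creatine kinase gene Ckb (2.72 against 0.50, 4.70-fold), Lgi1 (4.66-fold), the phosphatase gene Ptpn22 (4.40-fold), Serpina1e (1.86 against 0.370, 4.17-fold) and Calb1 (4.05-fold). The neurotrophin gene Ntf3 was 3.98-fold and the carbonic anhydrase gene Car2 3.50-fold higher. Of 12 measured secreted products 3 were higher in cluster 1, Serpina1e, Ovgp1 (3.77 against 1.38) and Wfdc2 (19.6 against 8.62), and 9 were within 2-fold (median log2 fold 0.13). Wnt7a, which patterns the Müllerian duct, stood at 0.574 against 0.151. Cluster 0 carried the genes of cells that are forming cilia. Foxj1 was 4.13-fold lower in cluster 1, and Deup1, needed to build many centrioles, had 1 count there (ratio interval of cluster 0 over cluster 1, 7.55 to 1720).

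Wt1 was 2.09-fold lower in P4 cluster 1, at 0.679 (0.495 to 0.909) against 1.53 (1.33 to 1.74). Pax2 went the other way, at 0.392 against 0.137 (ratio interval 1.54 to 5.41), while Pax8 stood at 1.33 against 1.40. Of 9 measured Hox genes 2 were higher in cluster 1, Hoxb6 (0.936 against 0.397) and Hoxb7 (0.649 against 0.274), 2 lower, Hoxc4 (0.196 against 0.513) and Hoxc5, and 5 within 2-fold. All 9 measured multiciliated markers (median −1.59) and 5 of 6 multiciliated precursor genes (median −1.82) were lower in cluster 1. All 10 proliferating markers and all 14 imprinted and fetal growth genes were within 2-fold. Dissociation stress genes were at least 2-fold higher in cluster 1 for 2 of 14, Hspb1 and Nr4a1. Still, 12 of the 14 had a log2 fold above 0 (median 0.61, percentile 100 among random lists). Without cells that carried 2 or more non-epithelial markers only 13 cells were left in each cluster, and there the log2 fold of Pax2 turned from 1.06 to −0.25, while that of Wt1 went from −1.06 to −1.83. P4 cells had a UMI of the fibroblast collagen gene Col1a1 in 75.6% and 70.5% of cells of clusters 0 and 1, a like share in both. Background RNA was not measured, so this share does not tell free RNA from expression by these cells.

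Much of the ciliogenesis signal at P4 came from 6 cells, singled out after their values were seen. They held 51.8 to 172.7 UMI of multiciliated markers per 10000, against at most 29.6 in the other P4 cells, and all 6 lay in P4 cluster 0. They held 62.5% of all P4 UMI of Deup1, 53.7% of Mcidas, which switches on the multiciliated program, and 40.1% of Foxj1. Their Foxj1 level, 7.73, was near that of adult multiciliated-like cells (7.56), but Tmem212 (2.58 against 16.6) and Ccdc153 (8.04 against 25.7) were lower. Early genes were higher than in the adult cells: Myb at 6.39 against 0.531 and Ccno at 4.12 against 0.0699. Without these cells the log2 fold of Foxj1 between the P4 clusters shrank from −2.04 to −1.40, with 0.719 left in cluster 0 against 0.211 in cluster 1, and Deup1 stood at 0.257 in cluster 0 against 0.0151 (1 count), while the log2 fold of Wt1 was −1.07 and that of Pax2 1.0.

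P4 and adult cells were compared on the 26897 genes that both tables hold (1839488 UMI in 263 P4 cells, 1376605 UMI in 406 adult cells). The libraries differ in age and also in library, sort, depth and annotation. The adult library was made at estrus, so estrous stage cannot be told apart from age either. Some fetal growth genes were counted at P4 alone: Dlk1, an imprinted gene related to Notch ligands, stood at 2.81 (2.57 to 3.06) and had 0 adult counts (at least 129.0-fold), and the imprinted RNA gene H19 at 2.04 and 0 (at least 93.5-fold). The growth factor gene Mdk was 17.5-fold, the prostaglandin D synthase gene Ptgds 13.9-fold, the histone gene Hist1h2ap 14.3-fold and Wfdc2 6.84-fold higher at P4. Adult secreted proteins were far lower: Wfdc18 stood at 0.50 against 37.2 (62.2-fold), Ovgp1 at 2.45 (2.23 to 2.69) against 42.4 (41.3 to 43.5; 16.6-fold) and Lcn2 at 0.359 against 7.90 (17.4-fold). Spp1, the secreted phosphoprotein osteopontin, had 2 P4 counts (ratio interval of adult over P4, 84.8 to 2551).

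Among the regional transcription factors, 3 of 10 were higher at P4, 3 lower and 4 within 2-fold (median 0.54). Pax8 was 2.84-fold higher at P4 (1.59 against 0.494) and Pax2 stood at 0.25 against 0.0508 (ratio interval 2.21 to 12.9), while Wt1 was 2.28-fold lower (1.46 against 3.45). Epcam stood at 5.39 against 5.16. All 7 measured Hox genes were within 2-fold (median 0.17).

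Of 12 measured imprinted and fetal growth genes 11 were higher at P4 (Dlk1, H19, Sox11 and Meg3 among them), with a median log2 fold of 2.59, and of 2.59 with the 3 genes at 0 adult counts set at their bound. Of 10 proliferating markers 9 were higher (median 2.07), with Top2a, which untangles DNA in dividing cells, at 1.05 against 0.0218. All 15 multiciliated markers were lower (median −3.07), as were 9 of 14 secreted products (median −1.90, with Wfdc2 and Cp the 2 that were higher), while 3 of 4 multiciliated precursor genes were higher (1.44). The steroid hormone list had 4 of 10 genes lower, such as Ltf and Areg, and 1 higher, the progesterone receptor gene Pgr (median −0.56). Of 8 stem and basal cell candidates 5 were lower and 2 higher (median −1.31). Wnt genes were higher for 5 of 11 and lower for 2 (median 0.46), with Wnt7a counted 0 times in the adult library (at least 15-fold) and Wnt4 lower (0.294 against 1.30). Extracellular matrix and adhesion genes were higher for 4 of 14 and lower for 2 (0.60). Retinoic acid (3 of 7 higher, 0.19), Notch (1 of 6 lower, 0.31) and Tgfb and Bmp genes (2 of 11 higher, 0.30) had medians near that of all measured genes (0.09). Dissociation stress genes did not move as a group (12 of 14 within 2-fold, median 0.04), and of 9 antigen presentation and interferon genes 1 was higher and 2 lower (−0.22).

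Genes encoded by the mitochondrial genome were lower at P4 for 10 of 13 (median −1.76), and 13 of 82 ribosomal protein genes were higher (0.81). Against adult secretory-like cells only 1 of 82 ribosomal protein genes was higher, with a median of 0.26 for all P4 cells and 0.19 for P4 cluster 1. A denominator without ribosomal and mitochondrial genes raised the median of all 7188 genes compared from 0.08 to 0.22, a shift of 0.13 in that median. Smooth muscle markers were lower for 3 of 5 (−1.57), but adult cluster 5 held 212 of the 301 adult counts of Tagln, and against adult secretory-like cells the median of all P4 cells was 0.51, with 1 of 5 higher. Stromal markers were higher for 4 of 6 (1.18), of mesothelial markers 2 of 3 were higher (1.38), and of epithelial markers 1 of 8 was lower (0.02). Secretory markers were split, 2 higher and 1 lower of 7 (0.69). Against adult secretory-like cells their sign turned: 1 was higher and 2 lower of 7, with a median of −0.34 for all P4 cells and −0.33 for P4 cluster 1. The 2 measured Hedgehog (−0.05) and 2 endothelial genes (0.50) stayed within 2-fold, and no immune or red blood cell marker reached the detection filter.

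**Figure D2:**
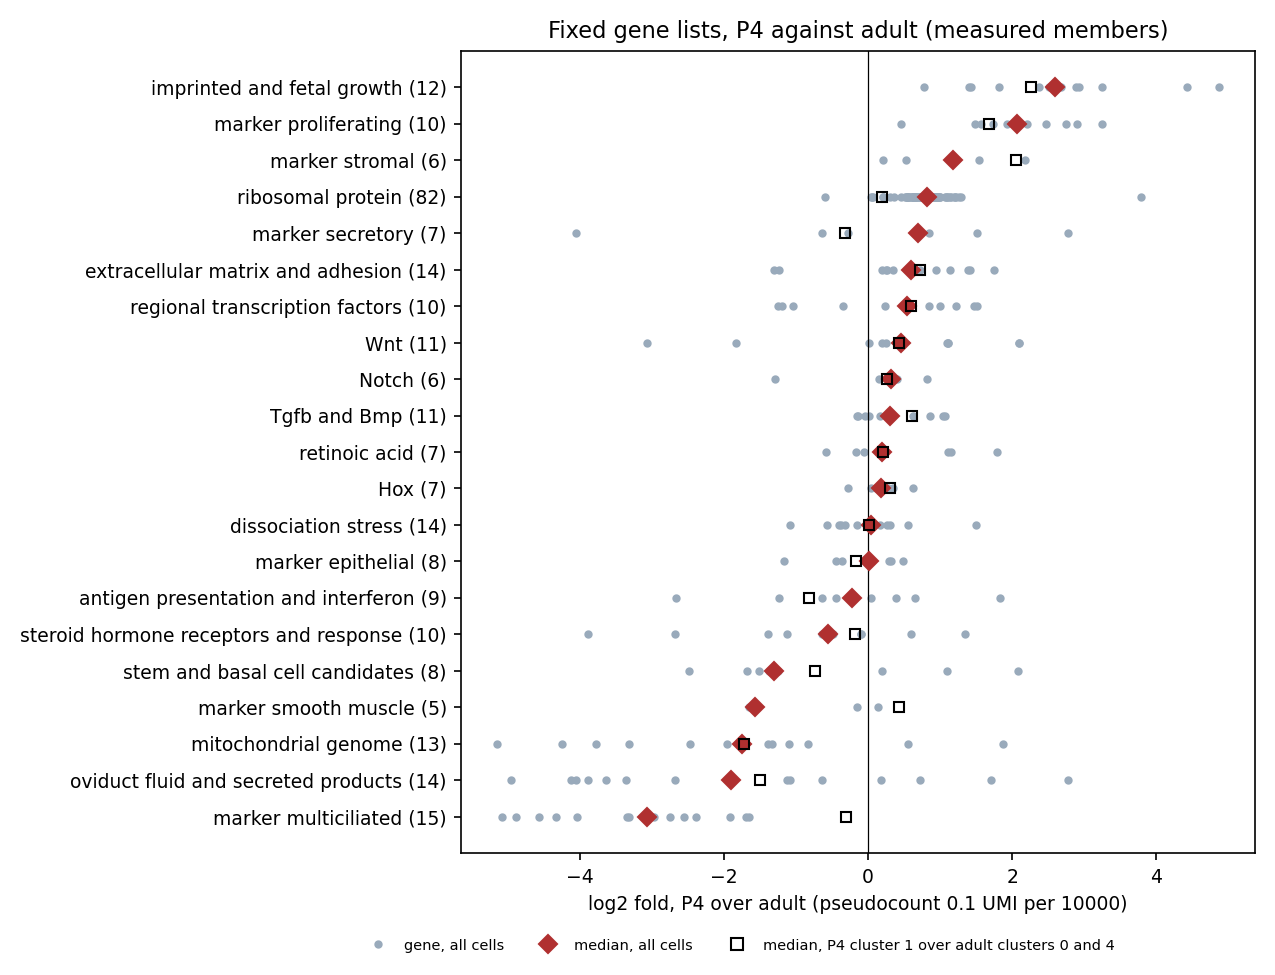
Each grey point is the log2 fold of a measured gene, P4 over adult, by fixed gene list; red diamonds are medians over all cells and open squares medians of P4 cluster 1 over adult clusters 0 and 4. Imprinted and fetal growth genes lie to the right (median 2.59) and secreted products to the left (−1.90) in both comparisons, while the multiciliated median of −3.07 over all cells is −0.30 between the secretory-type clusters.

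Between the secretory-type clusters alone (95 P4 cells against 161 adult cells), Ovgp1 was 18.9-fold lower at P4 (4.34 against 83.9), Wfdc18 322.9-fold lower, Ltf 43.9-fold and Lcn2 52.9-fold lower, and Dcpp3 at least 340.1-fold. Higher at P4 were the cyclin gene Ccnd2 (23.5-fold), Ifitm1 (21.4-fold), Wfdc2 (11.7-fold) and Serpina1e (8.60-fold). All 13 measured imprinted and fetal growth genes were higher (median 2.25, the same with the 5 genes at 0 set at their bound), as were 8 of 10 proliferating markers (1.68) and 3 of 4 stromal markers (2.05), while 9 of 12 mitochondrial genes were lower and 1 higher (−1.72). Secreted products were lower for 8 of 14 and higher for 4 (−1.49), and antigen presentation and interferon genes lower for 3 of 8 and higher for 1 (−0.82). Wt1 stood at 0.780 against 3.65, a log2 fold of −2.09 against −1.19 over all cells. Pax8 stood at 1.53 against 0.745, a 1.93-fold difference and so within 2-fold here. Multiciliated markers had a median of −0.30 here, and of 1.28 when all P4 cells were set against the adult secretory-like cells. Secretory markers hardly set P4 cluster 1 apart from P4 cluster 0, so this comparison may not be of like cell classes. No multiciliated class was compared between ages, since only 6 P4 cells exceeded 30 UMI of these markers per 10000 (median over all P4 cells 1.65, against 210.9 in adult cluster 1).

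The authors' merged table placed P4 cells apart from adult cells. Merged cluster 1 held 225 P4 and 2 adult cells (99.1% P4, 96.9 to 99.9) and merged cluster 0 held 197 adult and 14 P4 cells, while clusters 2, 4 and 6 (98, 85 and 21 cells) held adult cells alone. Of the P4 cells 94.1% (90.4 to 96.8) lay in merged cluster 1, 137 of 148 from P4 cluster 0 and 88 of 91 from P4 cluster 1. The division into P4 clusters was thus not kept in the merged clusters (adjusted Rand index −0.02), whereas that of the adult cells was kept in part (0.657). Of the adult multiciliated-like cells in cluster 1, 178 of 182 lay in merged cluster 0, the cluster that also took the 6 P4 cells with cilium genes. Adult cluster 0 was divided between merged clusters 2 (79 of 128 cells) and 4 (49), and cluster 3 between merged clusters 0 (17 of 36) and 6 (19). Cluster 5 lay mostly in merged clusters 2 (12 of 25) and 4 (11), and 24 of 31 cells of cluster 4 lay in merged cluster 4.

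**Figure D3:**
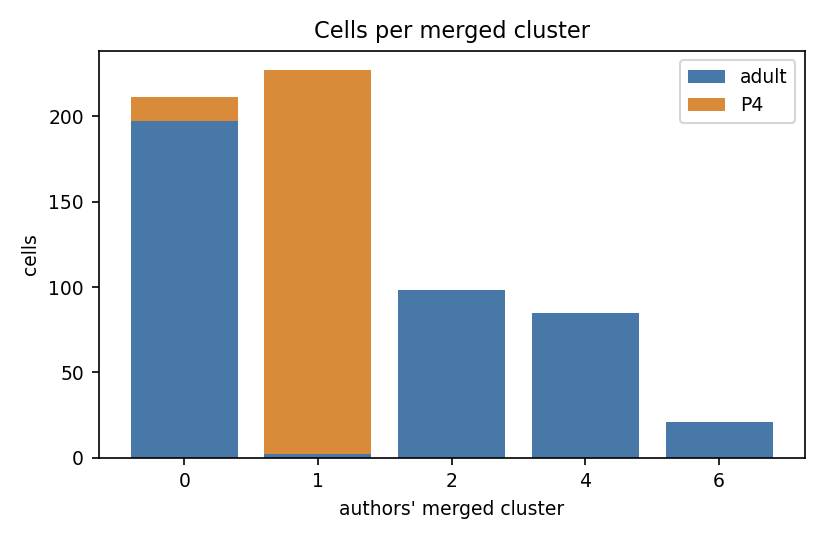
Bars count the adult and P4 cells in each of the authors' merged clusters. Merged cluster 1 is almost wholly P4 (225 of its cells), merged cluster 0 is mostly adult (197) with 14 P4 cells, and clusters 2, 4 and 6 hold adult cells only.

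Cells with at least 3 of the 10 proliferating markers made up 92 of 263 P4 cells (35.0%, 29.2 to 41.1) and 1 of 406 adult cells (0.246%), with median depths of 7585 and 3232 UMI. Thinned to 1000 UMI per cell the shares were 1.90% (0.620 to 4.38) and 0.311% (0.00786 to 1.72), so at equal depth the intervals overlapped. Few cells reach 3 markers at that depth. Top2a alone had a UMI in 9.13% (5.93 to 13.3) of thinned P4 cells and 0.311% (0.00786 to 1.72) of thinned adult cells. Mki67 had one in 3.04% (1.32 to 5.91) and in 0 of 322 (up to 0.932%). For these single genes the intervals did not overlap. Within P4 the shares were 39.9% in cluster 0 and 26.3% in cluster 1. The pooled levels of Top2a and the other markers do not depend on such a threshold.

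Wt1 and Pax2 were examined in the same cells, since this needs no clusters. In the adult library Wt1 had a UMI in 206 cells (50.7%, 45.8 to 55.7) and Pax2 in 7 (1.72%, 0.696 to 3.52), and 4 cells had both, with 3.55 expected from independent detection. At P4 Wt1 had a UMI in 149 cells (56.7%, 50.4 to 62.7) and Pax2 in 44 (16.7%, 12.4 to 21.8), and 21 cells had both, with 24.9 expected. Neither library therefore showed exclusion beyond counting error, but with 3.55 cells expected the adult library could hardly have shown it. The expected numbers also ignore that depth differs between cells, which raises joint detection and can hide exclusion. The macrophage gene Lyz2 had a UMI in 1.72% of adult and 1.14% of P4 cells, and the fibroblast gene Col1a1 in 10.6% and 73.8%. The adult Pax2 share is therefore no higher than that of a gene of another cell type, and the P4 shares alone do not show expression. The difference in Wt1 between the P4 clusters is larger than evenly spread RNA gives: it had a UMI in 70.2% (62.7 to 77.0) of cells of P4 cluster 0 and 32.6% (23.4 to 43.0) of cluster 1, at median depths of 7856 and 7029 UMI, and Pax2 in 11.9% and 25.3%. Among adult clusters 0, 1, 3, 4 and 5 the share with Wt1 was 61.5%, 57.4%, 24.3%, 16.1% and 28.0%. Their median depths were 4107.5, 3165, 3657, 1185 and 4085 UMI, so the low share of cluster 4 goes with low depth. In the 18 cells of cluster 5 without smooth muscle genes the share was 5.56%. At 1000 UMI per cell Wt1 had a UMI in 27.0% of adult and 9.89% of P4 cells.

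If the division at P4 were the adult one, genes should differ between clusters in the same direction at both ages. Between adult cluster 4 over 0 and P4 cluster 1 over 0 the log2 folds of 4186 genes had almost no relation (Pearson r 0.03, Spearman rho 0.02). This r cannot decide whether the divisions differ, because cluster 4 held only 31 cells and 61113 UMI. A count of 3 equals 0.491 per 10000 there, and counting error in the folds of low genes lowers r. The r that a shared division would give at this depth was not computed. With the stricter filter on the share of cells r was higher but still low. Adult cluster 4 over 0 was the planned pair. In all, 4 pairs were computed, and genes are not independent replicates. Of the genes with the largest adult folds 12 of 21 had the same sign at P4, and of those with the largest P4 folds 5 of 8 had the same sign in the adult. Wt1 was lower and Hoxb6, Calb1 and Ovgp1 were higher in the first cluster of both pairs. The pairs added later gave r 0.245 (rho 0.173, 4549 genes; same sign for 10 of 13 adult and 9 of 15 P4 genes) for adult cluster 3 over 1, 0.109 (8 of 15 and 10 of 16) for cluster 5 over 0, and 0.187 for cluster 5 without its smooth muscle cells. In cluster 3 over 1 as at P4, Wt1 was lower and Hoxb6 and Hoxb7 higher. Dissociation stress genes had positive median log2 folds in both (1.5 and 0.61), and multiciliated markers negative ones (−0.43 and −1.59). The r of cluster 3 over 1 was not computed without these genes. In the 18 cells of cluster 5 Serpina1e and Wfdc2 were higher, as in P4 cluster 1. The genes named in this paragraph were picked after their values were seen.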

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

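The tests of the repeated barcodes and of the smooth muscle genes were chosen after the results were seen, and those of the separation of P4 cells before the neighbour shares were computed, though the merged clusters were known. The tables hold 3 signals outside the main comparisons: 401 adult barcodes that occur in both sets of columns, 13.4% of P4 UMI on genes that the adult table lacks, and 24 P4 cells that the merged table leaves out. No group has enough samples to look for an outlying sample, and with 1 library per age no difference between the ages in a contrast of clusters could be tested.

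The 401 repeated barcodes could be separate cells that share a barcode, but the mean squared difference over the sum of their paired counts was 0.140, where separate cells of a cluster gave 1.40 to 1.77. Of the gene and cell entries seen in either set 88.8% were seen in both, against 19.5% to 21.6% for other pairs, which is what the same cells counted in both sets would give. The totals had ratios of 0.974 to 1.04, and 399 pairs had the same cluster, but 0 pairs were identical in every gene. Whether the same library was sequenced again or processed again stays open, and no biological explanation was tested.

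The smooth muscle genes of adult cluster 5 may come from smooth muscle and epithelial cells caught in the same droplets. Free RNA reaches all cells of a cluster alike, but 28% of its cells held 10 or more UMI of these genes, at 42 to 156, and the others at most 4. The 7 cells had a median of 7757 UMI, above the 3232 of the library, and a median Ovgp1 level of 26.4, against 0 in multiciliated-like cells. Acta2, Tagln and Myh11 stood at 48.4, 35.8 and 12.4 in them, Epcam at 2.59 against 4.81 in the other 18 cells, and the cilium genes Foxj1 and Tmem212 at 2.76 and 2.07 against 0 and 0.370, so some of these droplets also held multiciliated RNA. An epithelial cell that itself makes contractile proteins stays open, as untested, and the sort for Epcam would remove smooth muscle cells on their own.

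P4 cells lay apart from the adult cells of clusters 0, 4 and 5 (449 cells with the P4 cells; adult multiciliated-like cells were left out of this test). Among the 15 nearest neighbours of P4 cells the median share of P4 cells was 100% on the shared genes alone, where the genes present in only one of the tables were left out, 100% with cells thinned to 1000 UMI, and 100% on the fixed lists without ribosomal and mitochondrial genes. The means were 99.8%, 99.7% and 95.3%, against 58.6% by chance (63.7% after thinning), so none of these is the sole cause. Age against library cannot be told apart, since there is 1 library per age, and an age difference therefore stays open, as untested.

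Of the P4 UMI on genes that the adult table lacks, 55.1% lay on Gm models and 29.6% on symbols of processed pseudogenes or retro copies. Rps27rt stood at 49.9 per 10000 at P4 and 1.74 in the adult library, beside Rps27 at 81.7 and 54.5, and Rps26-ps1 at 15.3 and 0.193, beside Rps26 at 33.2 and 17.7. The merged table holds 148 of the 168 cells of P4 cluster 0 and 91 of the 95 of P4 cluster 1. Most P4 cells outside it are thus of cluster 0, and the P4 clusters were not compared without them. The 24 P4 cells outside the merged table had no Epcam UMI in 12 cases (50%, 29.1 to 70.9), against 8% (4.81 to 12.3) of the 225 P4 cells in merged cluster 1. Their immune marker level was 2.82 against 0.252 and their endothelial level 2.60 against 0.471, and 3 of them had 4 or more immune UMI, although the sort used CD45 antibodies.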

How the results depend on the processing

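The alternatives that used other adult columns, other classes of clusters, other pairs across genes, or left out P4 cells with multiciliated markers were chosen after seeing the data. Of 1003 alternative values for 118 results, the 23 results that answer a comparison have 170, of which 114 stayed within counting error (counts of genes within 1.5 times), 54 moved and 2 reversed. The 95 others have 833: 582 stayed, 249 moved and 2 reversed. Some values in both sets could not move, or hardly could. Without the filter on the share of cells, folds of single genes are the same values by construction. The other choices of adult columns recount mostly the same cells. The numbers that stayed are therefore not a measure of robustness. No paired analysis was possible because each age has a single library, with replicate number 1. Where construction does not show it, the cause was not tested.

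With every cell weighing alike, the log2 fold of Ovgp1 was 3.98 between secretory-like and multiciliated-like cells, 2.76 for adult cluster 4 over 0 and −4.24 for P4 over adult. Wt1 was −1.46 between P4 clusters and −0.91 for P4 over adult, and the multiciliated median −4.81 (adult classes) and −4.03 (P4 over adult). Of 24 named genes for adult cluster 4 over 0 it kept 12. A pseudocount of 0.5, which shrinks folds of low genes by construction, gave multiciliated medians of −3.94 and −2.53, an imprinted median of 1.26 and Ovgp1 at −3.86 for P4 over adult, and kept 15 of the 24 named genes of the P4 clusters. No filter on the share of cells gave an imprinted median of 2.10.

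Leaving out cells with non-epithelial markers gave Ovgp1 at 3.46 (adult classes), 2.39 (cluster 4 over 0) and −3.72 (P4 over adult). In P4 it left 13 cells per cluster: Wt1 went to −1.83, Pax2 reversed to −0.25, and 1 of the named and 1 of the 16 defining genes were kept. For P4 over adult it left 26 P4 cells, with Wt1 at −1.84, the imprinted median at 3.04 and the multiciliated median at −3.49. Leaving out the 5% of cells with the most UMI gave Ovgp1 at 3.39 (adult classes) and a multiciliated median of −4.11 (P4 over adult), and kept 14 named and 7 defining genes of the P4 clusters. Leaving out the 6 P4 cells with multiciliated markers also kept 14 and 7.

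For P4 over adult, thinning gave Wt1 at −1.47, the imprinted median at 3.64 and the multiciliated median at −3.97. The denominator without ribosomal and mitochondrial genes gave Ovgp1 at −3.92 and the imprinted median at 2.90. The merged table gave an imprinted median of 2.35 and kept 3 of 24 named genes, because 21 of its own lie in only 1 single table. Without proliferating cells the multiciliated median was −3.94. Secretory-type clusters alone gave Ovgp1 at −4.24, Wt1 at −2.09, imprinted 2.25, multiciliated −0.30 and 10 named genes. All P4 cells against adult secretory-like cells gave Ovgp1 at −5.04, imprinted 2.17 and 11 named genes, and reversed the multiciliated median (1.28), Tmem212 (0.019) and Ccdc153 (0.19), since the adult multiciliated cells are left out.

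With cluster 1 alone as multiciliated Ovgp1 was 3.72, and with cluster 0 alone as secretory 2.64. All deposited adult columns kept 12 named genes for cluster 4 over 0. Own Leiden clusters put 34.0% of adult cells in the largest cluster (reported 45.1%) and 97.5% of P4 cells in 1 merged cluster (reported 94.1%). The r across genes was 0.0894 with genes in 25% of cells, 0.109 for adult cluster 5 over 0, 0.187 for it without smooth muscle cells and 0.245 for cluster 3 over 1.

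Depth limits the search for cells with both Wt1 and Pax2: at 2 or more UMI, after thinning, and in adult secretory-like cells under 1 such cell is expected, so these alternatives gave no value. In P4 cluster 1 the observed over expected number was 1.15, against 0.842 for all P4 cells. Values on a log scale do not occur, so that alternative was not run.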

Other observations

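Retinoic acid signalling, which patterns the reproductive tract, showed few differences inside the P4 library: of 8 measured genes 1 was higher in cluster 1, Crabp2, 1 lower and 6 within 2-fold. Extracellular matrix and adhesion genes were higher in P4 cluster 1 for 1 of 14, Ncam1, with a median log2 fold of 0.40 and 13 within 2-fold. Of 9 regional transcription factors 2 were higher there, Pax2 and Dach1, and 2 lower, Wt1 and Nr2f1. The steroid hormone list had all 9 measured genes within 2-fold (median 0.37).

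Own clusters of the merged cells put 233 P4 and 3 adult cells together and 6 P4 cells apart, and these 6 were the cells with multiciliated markers. The adjusted Rand index of own against the authors' clusters was 0.542 for adult cells, 0.663 for P4 cells and 0.794 for merged cells.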
